A study of Mus musculus with 9 samples.

How the data were processed

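Oligo(dT)-primed RNA of 9 samples of mouse bone-marrow-derived macrophages was sequenced in pairs of 150-base reads on a HiSeq instrument, with 3 libraries each for the PD-L1 antibody, the isotype antibody and no antibody. All libraries came from 1 flow cell, and by the deposited names PD-L1 antibody 2 was read in lane 4 and the others in lane 1. The authors named Partek and STAR without versions, without saying which step each did, and without a genome build. Transcript positions matched GRCm38, since 21711 of 21923 gene symbols found in GENCODE M21 (99.0%) overlapped the gene of that name.

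For each library the files list RefSeq transcripts. The deposited read counts are, as tested on the files, the reads over each transcript's whole genomic span, introns, overlapping genes and spliced gaps included, and isoforms repeat the same reads: 4611 of 4738 sets of isoforms with 1 span had 1 read number in every library. Average coverage, the signal per exonic base, and total exon length are given per the file headers. The GC percent values are, per the file headers, the GC percentage for each transcript. Transcripts without exonic coverage are absent. Mitochondrially encoded genes were not in the files, so the list of mitochondrial mRNAs could not be tested.

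The values analysed were exonic read equivalents, average coverage times total exon length divided by the read length of 150, with 1 transcript per gene symbol. They came to 67.74 to 70.6% of the reads over gene spans, and totals per library ran from 23554320 to 40116467. Of 35131 transcripts of 22376 genes, 13728 genes passed edgeR's filterByExpr. Libraries were scaled by TMM, values turned into log2(CPM + 1), with CPM the exonic reads per 1e+06 of the library's total over tested genes times its TMM factor (0.919 to 0.932 in the PD-L1 antibody libraries, 1.009 to 1.063 in the others), and all 9 libraries fitted in limma with a trended variance and 1 mean per group. Each pair of groups was compared by limma's moderated test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Depth limits low genes most, and PCR reads without molecular identifiers are not independent molecules.

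This departs from the design fixed before the data were examined, which summed deposited read counts per gene symbol and tested them with edgeR's quasi-likelihood test. The change was made after the data were seen, and after the numbers of genes called by several versions had been looked at. The reason was what the deposited read counts hold: introns, neighbouring genes, repeated counting and absent transcripts. The design as first fixed called 4159, 4898 and 2 genes in the 3 comparisons, against 5002, 5830 and 1 in the analysis reported. The gene lists, the comparisons, the rule for named genes and most alternatives were also fixed before the data were examined and were kept.

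The rule named Cd274, Pdcd1, Pdcd1lg2 and Cd80 in every comparison. It added the 8 largest rises and 8 largest falls (4 and 4 against untreated wells) among genes that passed, whose libraries did not overlap between groups and whose mean was at least 5 CPM, leaving out unnamed and pseudogene symbols. From each list described it took 2 to 4 of the tested members with the lowest p. Of 29 gene lists (signalling, metabolism, stress, antigen presentation and markers of other cell types) 28 could be tested, by camera with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Members of a list were also adjusted over the list alone.

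The 2 antibody effects were compared against 100 simulated draws with shared controls. Alternatives were other scalings, filters, tools (edgeR, DESeq2, limma-voom), pseudocounts, a threshold of 0.01, and leaving out each library. The procedure was tested on simulated data: in the comparison of the 2 antibodies it called 42.9% of genes changed 1.5-fold, 77.6% changed 2-fold and none changed 1.25-fold in the right direction, and 9 of 13374 unchanged genes. Only 200 genes were changed there, balanced between rises and falls, far fewer than the PD-L1 antibody comparisons called. These rates may therefore differ in the real data. The software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.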

Results

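RNA sequencing was carried out on mouse bone-marrow-derived macrophages, the cells that grow out of marrow cultured with macrophage colony-stimulating factor (M-CSF). The marrow came from wild-type C57Bl/6 animals and was cultured for 1 week with 10 ng/ml M-CSF, after which 50000 cells were plated for 48 h. There were 3 groups of 3 libraries: wells given 100 µg/ml of an antibody against PD-L1 (libraries 1 to 3), wells given 100 µg/ml of an isotype antibody, which has no intended target (libraries 4 to 6), and untreated wells (libraries 7 to 9). PD-L1, the product of Cd274, is a surface ligand of the T cell inhibitory receptor PD-1. Exonic read equivalents, with 1 transcript per gene symbol, ranged from 23554320 per library (untreated 7) to 40116467 (untreated 9), and 13728 genes were tested. Values are CPM (exonic read equivalents per 1e+06 of the library's total times its TMM scaling factor), as mean ± SD with n = 3. Log2 fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. The labels do not say whether the wells came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

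The first principal component held 72.1% of the variance and placed the 3 PD-L1 antibody libraries at 46.35 to 49.53 and the other 6 between -30.93 and -19.83. Component 2 held 12.3% and placed untreated 8 and 9 at 22.76 and 22.5, while untreated 7 lay at -15.82, within the range of the isotype antibody libraries (-18.68 to -3.21).

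**Figure D1:**
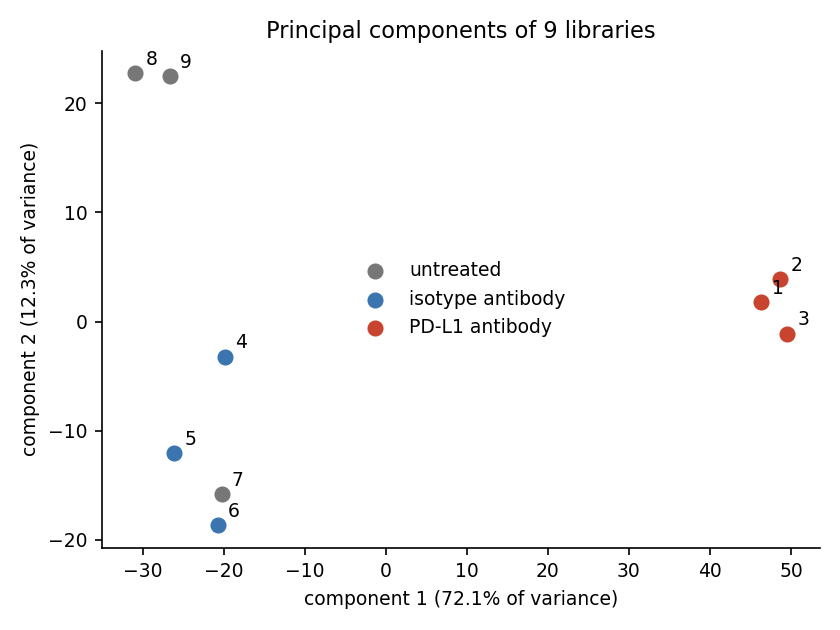
Principal components of the 9 libraries, with component 1 (72.1% of the variance) on the horizontal axis and component 2 (12.3%) on the vertical axis; each point is a library with its replicate number. The PD-L1 antibody libraries stand at 46.35 or more on component 1, and untreated 7 lies apart from untreated 8 and 9 on component 2.

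The comparison of PD-L1 antibody with isotype antibody asks what the target-directed antibody changed beyond antibody protein as such. It also takes in any other difference between the antibody preparations, without separating it from binding of PD-L1. With the PD-L1 antibody the largest rise by the rule for named genes was that of the acute-phase protein gene Saa3 (11000 ± 905 against 89.49 ± 64.3 CPM, log2 fold change 7.17, SE 0.45). Il1a and Il1b, which encode the interleukin-1 cytokines, rose by 5.14 and 4.14 on the log2 scale, and Nos2, the inducible nitric oxide synthase, by 5.37. Of the interferon-stimulated genes 33 of 34 rose, of MHC class I genes 17 of 18 and of glycolysis genes 17 of 20 (adjusted p = 0.22, 0.22 and 0.185 with an estimated correlation). Falls were called in 9 of 11 MHC class II, 26 of 43 cell cycle and 15 of 26 lipid-handling genes, with 0, 2 and 2 rises (adjusted p = 0.22, 0.261 and 0.338 with an estimated correlation). In all, 5002 of 13728 genes (36.4%) changed at an adjusted p under 0.05 in limma with Benjamini-Hochberg adjustment, 2502 higher and 2500 lower, and 599 of the rises and 505 of the falls were at least 2-fold.

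The target transcript itself, Cd274 (chromosome 19, 29367438 to 29388094, plus strand), stood at 662.5 ± 93 CPM with the PD-L1 antibody and 226.5 ± 44.6 CPM with the isotype antibody, a log2 fold change of 1.55 (SE 0.15, limma adjusted p = 1.6e-05). The rise was seen in all 3 libraries. Cd80, a co-stimulatory ligand that also binds PD-L1, rose from 7.342 ± 0.372 to 14.64 ± 3.16 CPM (log2 fold change 0.89). Pdcd1lg2, which encodes the second PD-1 ligand, was low and rose from 0.6906 to 1.638 CPM (limma adjusted p = 0.0245), a call that was lost without PD-L1 antibody 2, isotype 5 or isotype 6. Pdcd1, which encodes PD-1, was at 0.5583 and 0.3792 CPM (limma adjusted p = 0.515).

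By the rule for named genes, the 8 largest rises were Saa3, Cd38 (log2 fold change 6.1), Serpinb2 (5.93), Nos2 (5.37), Ptges (5.17), Slfn4 (5.17), Fpr1 (5.15) and Il1a (5.14). Cd38 encodes an NAD-consuming surface enzyme, and its level went from 1.762 ± 0.817 to 184.3 ± 25.7 CPM. Ptges, the terminal prostaglandin E synthase, went from 5.375 ± 1.13 to 230 ± 50.6 CPM, and Fpr1, a receptor for bacterial formyl peptides, from 4.5 ± 1.38 to 191.7 ± 28.4 CPM. The 8 largest falls were Gprc5c (-3.78), the organic anion transporter gene Slco2b1 (-3.77), Nptx1 (-3.58, a call lost with limma-voom on deposited read counts), Mamdc2 (-3.56), Pcp4l1 (-3.43), Shisa9 (-3.17), the cyclin-dependent kinase inhibitor gene Cdkn1c (-3.12) and the co-stimulatory receptor gene Cd28 (-3.1). Cd28 fell from 144.5 ± 12.8 to 15.93 ± 1.23 CPM, and Cdkn1c from 53.26 ± 3.64 to 5.311 ± 1.11 CPM. The genomic span of Il1a, introns included, overlaps that of another annotated gene. The same holds for Il1b, Cxcl10, Tnfsf9, Ccnd2, Cdc20, Gadd45a, Deptor and C3, described further on. Overlap of exons was not checked, so the reads of these genes could not be assigned with certainty.

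Among 23 tested inflammatory cytokine and chemokine genes 21 rose and none fell, with a median log2 fold change of 1.8. Besides the interleukin-1 genes they included Il1rn, the interleukin-1 receptor antagonist (52.19 ± 9.77 to 913.4 ± 197 CPM), and the neutrophil-attracting chemokine gene Cxcl1 (0.8691 ± 0.221 to 13.01 ± 2.09 CPM). The list lay above other genes (camera adjusted p = 2.18e-14), with an adjusted p = 0.146 when the correlation between its genes was estimated. In the list of NF-kB feedback and inflammatory response genes 17 of 20 rose and none fell. Sod2, the mitochondrial superoxide dismutase, went from 103.8 ± 6.31 to 1008 ± 72.4 CPM, Marco, a scavenger receptor gene, from 1.809 ± 0.815 to 66.67 ± 12 CPM, and the cyclooxygenase gene Ptgs2 from 5.492 ± 0.757 to 85.58 ± 19.4 CPM. Here camera gave an adjusted p = 4.06e-12, and an adjusted p = 0.22 with an estimated correlation. Adjusted over the list alone, 21 and 17 members of these lists rose.

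Of 34 interferon-stimulated genes 33 rose and none fell (median log2 fold change 1.25). Cxcl10, a chemokine induced by interferon, went from 27.17 ± 4.33 to 307.2 ± 53.7 CPM, and the guanylate-binding protein gene Gbp5 from 44.57 ± 9.03 to 240.5 ± 27.2 CPM. The camera adjusted p was 8.18e-20, with an adjusted p = 0.22 under an estimated correlation, and 33 rose when adjusted over the list alone. MHC class I presentation genes rose in 17 of 18 cases (17 adjusted over the list alone), with a median of 0.7, a camera adjusted p = 3.5e-09 and an adjusted p = 0.22 with an estimated correlation. H2-Q4 went from 315.7 ± 57.8 to 712.8 ± 29.8 CPM. H2-T22, H2-Q7 and H2-Q6 rose by 1.6, 2.12 and 2.19, but these near-identical genes can share reads and are uncertain one by one.

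MHC class II presentation went the other way, with 9 of 11 members falling and none rising (9 adjusted over the list alone, median -0.75). Of 13 dendritic cell markers 7 fell and 2 rose in the same comparison (8 and 2 adjusted over the list alone, median -0.74, camera adjusted p = 0.0947). Their summed level did not fall, at 1080 ± 79 CPM with the PD-L1 antibody and 908 ± 280 CPM with the isotype antibody. Some of these markers were low, such as Clec9a at 1.081 to 1.37 CPM with the isotype antibody. H2-Eb1 fell from 990.6 ± 183 to 401.4 ± 3.98 CPM, H2-Aa from 1057 ± 164 to 480.9 ± 22.9 CPM, and Ciita, the transcriptional activator of this class, from 110.6 ± 24 to 40.83 ± 1.57 CPM. For MHC class II the camera adjusted p was 2.38e-05, and the adjusted p = 0.22 with an estimated correlation. Among 18 co-stimulatory and checkpoint molecules 10 rose and 3 fell, the same counts as those adjusted over the list alone (camera adjusted p = 0.00928, adjusted p = 0.185 with an estimated correlation). Lgals9, which encodes galectin-9, rose by 0.99, Tnfsf9, the 4-1BB ligand gene, by 1.85 and the poliovirus receptor gene Pvr by 1.11.

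Glycolysis genes rose in 17 of 20 cases with none falling (18 adjusted over the list alone), at a median of 1.48; scaled by total counts, 1 fell. The glucose transporter gene Slc2a1 went from 37.22 ± 1.98 to 203 ± 12.3 CPM, the lactate exporter gene Slc16a3 from 61.01 ± 2.33 to 418.4 ± 40.4 CPM, and the phosphofructokinase gene Pfkl from 38.01 ± 3.05 to 193 ± 17.2 CPM. Camera gave an adjusted p = 2.18e-14, and an adjusted p = 0.185 with an estimated correlation. In the list of lipid handling and phagocytosis genes 15 of 26 fell and 2 rose, both over all genes and adjusted over the list alone (median -0.62, camera adjusted p = 0.000139, adjusted p = 0.338 with an estimated correlation). Trem2, a lipid-sensing receptor, fell from 858.3 ± 45.4 to 272.9 ± 23.7 CPM, lysosomal acid lipase (Lipa) from 1230 ± 118 to 369.8 ± 62.1 CPM and lipoprotein lipase (Lpl) from 1920 ± 328 to 502.9 ± 54.2 CPM. The scavenger receptor gene Msr1 was among the rises, from 192.4 ± 23.6 to 925.2 ± 44.4 CPM.

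**Figure D2:**
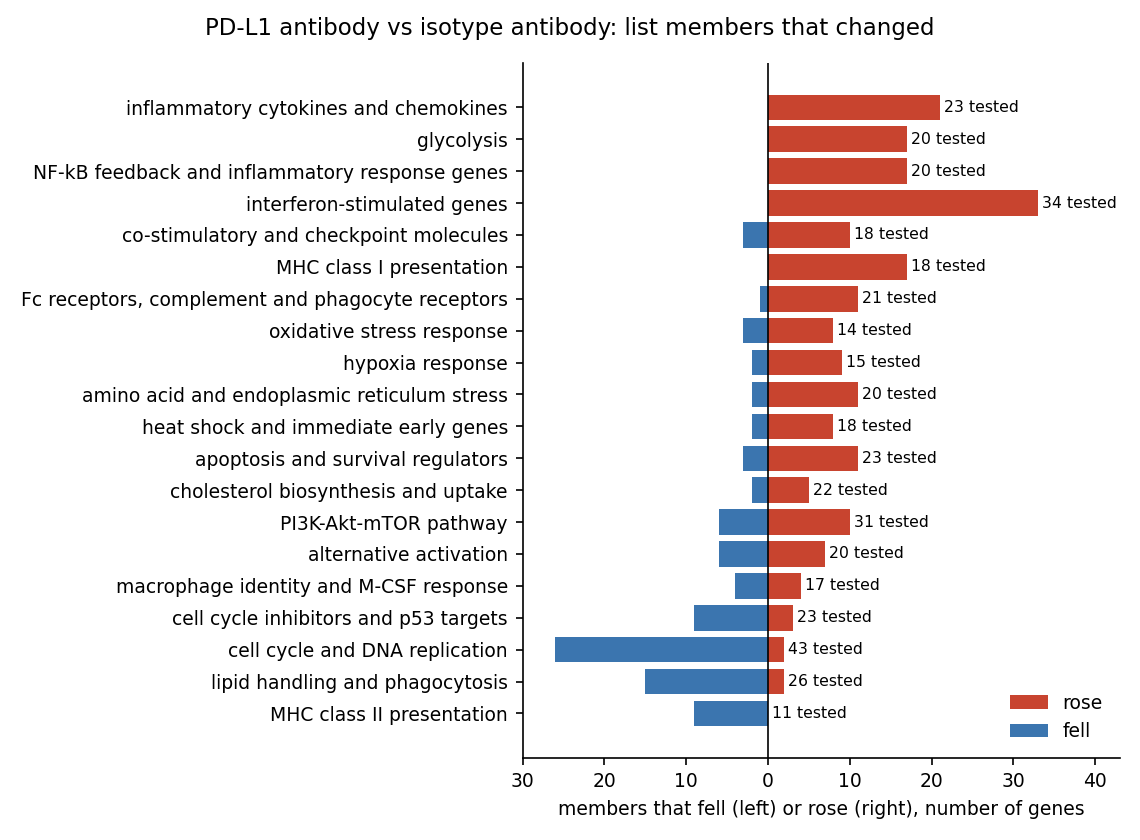
Number of genes in each fixed list that rose (bars to the right) or fell (bars to the left) in PD-L1 antibody against isotype antibody libraries at a limma adjusted p under 0.05, with the number tested at the bar's end. In the cytokine, glycolysis, NF-kB, interferon-stimulated and MHC class I lists no member fell, and in MHC class II no member rose; scaled by total counts, 1 glycolysis gene fell.

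Cell cycle and DNA replication genes fell in 26 of 43 cases and rose in 2 (28 and 2 adjusted over the list alone), at a median of -0.51. Ube2c, Rrm2 and Cdc20, which act in mitosis or nucleotide supply, fell by 1.4, 1.23 and 1.39, from levels of 6.098, 10.58 and 8.736 CPM. Ccnd2, the cyclin D2 gene, was one of the rises, from 27.62 ± 3.67 to 189.1 ± 20.4 CPM. Summed over the list, Ccnd2 included, levels differed little. They were 883 ± 23 CPM with the PD-L1 antibody, 919 ± 74 with the isotype antibody and 860 ± 68 in untreated wells. The camera adjusted p was 5.74e-07, and the adjusted p = 0.261 with an estimated correlation. Beside this list, summed neutrophil and granulocyte precursor markers stood at 692 ± 89 CPM with the PD-L1 antibody, 1120 ± 360 with the isotype antibody (1538 in isotype 4) and 797 ± 96 in untreated wells. The list of cell cycle inhibitors and p53 targets did not pass (camera adjusted p = 0.0646), with 9 of 23 members falling and 3 rising (9 and 4 adjusted over the list alone), among them Cdkn1c, Trp53inp1 (-1.32), Gadd45a (-1.32) and Sesn1 (-1.58).

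Among 23 apoptosis and survival regulators 11 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.338 with an estimated correlation). The death receptor gene Fas went from 4.187 ± 0.532 to 17.94 ± 1.79 CPM and Cflar, an inhibitor of caspase 8 activation, from 134.5 ± 18.8 to 378.1 ± 26.2 CPM, while the pro-apoptotic Pmaip1 fell from 58.18 ± 4.35 to 30.54 ± 0.372 CPM. The median of this list was 0.15 and turned to -0.03 when libraries were scaled by total counts only, where 6 members fell. Fc receptor, complement and phagocyte receptor genes rose in 11 of 21 cases and fell in 1 (the same adjusted over the list alone; camera adjusted p = 0.00012, adjusted p = 0.239 with an estimated correlation). Cd14, a co-receptor for bacterial lipopolysaccharide, rose by 1.71, Tlr2 by 1.53, and the integrin gene Itgam by 1.15; none fell without isotype 5, and 3 fell without untreated 7.

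The PI3K-Akt-mTOR list did not pass (camera adjusted p = 0.272), with 10 of 31 members rising and 6 falling (11 and 6 adjusted over the list alone). Ddit4, an mTOR inhibitor gene, rose by 1.94, and Deptor, also an mTOR inhibitor gene, fell by 1.28; without PD-L1 antibody 2 the falling members numbered 3. Alternative activation genes moved both ways, 7 up and 6 down of 20 (7 and 7 adjusted over the list alone; camera adjusted p = 0.998). Arg1, which encodes arginase 1, went from 0.1435 ± 0.0818 to 35.61 ± 9.93 CPM and Socs3, a feedback inhibitor of cytokine signalling, from 23.37 ± 2.21 to 505.9 ± 129 CPM, while the lectin genes Clec10a and Clec7a fell by 2.85 and 1.98. Macrophage identity genes also split, 4 up and 4 down of 17 (the same adjusted over the list alone; camera adjusted p = 0.61), with the F4/80 gene Adgre1 higher (1690 ± 169 to 4100 ± 65.6 CPM) and the transcription factor gene Cebpa lower (465.2 ± 89.8 to 118.6 ± 2.94 CPM); scaled by total counts, 7 were lower. Of 22 cholesterol genes 5 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.272); leaving out PD-L1 antibody 1, PD-L1 antibody 3, isotype 5 or isotype 6 left 2 rises, leaving out isotype 4 left 3, and total-count scaling left 1.

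Scaling by total counts moved the median of all genes by -0.17 and the split of calls to 1565 higher and 4148 lower. The design fixed beforehand, edgeR's quasi-likelihood test on deposited read counts summed over transcripts, called 4159 genes (1902 higher, 2257 lower), and 52.1% of genes had groups that did not overlap, against 10% by chance.

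**Figure D3:**
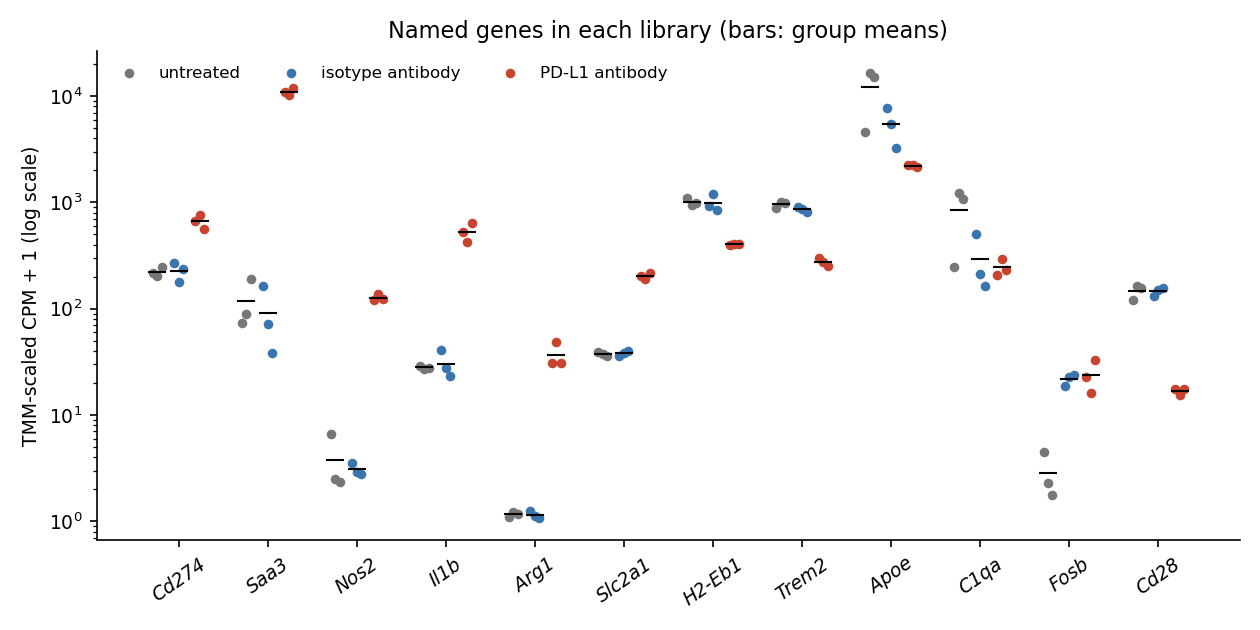
TMM-scaled CPM plus 1, on a log axis, of 12 named genes in each of the 9 libraries, with bars at the group means. Cd274, Saa3, Nos2, Il1b, Arg1 and Slc2a1 lie higher in all 3 PD-L1 antibody libraries than in the other 6, and for Apoe and C1qa untreated 7 lies with the isotype antibody libraries.

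Comparison of PD-L1 antibody with untreated wells takes in antibody protein, any binding of PD-L1 and anything else in the preparation, without separating them. Again Saa3 (11000 ± 905 against 116.4 ± 62.4 CPM, log2 fold change 6.67), Cd38 (5.77), Serpinb2 (5.72) and Fpr1 (5.43) were the largest rises by the rule. The largest falls were Slco2b1 (-4.16), Gprc5c (-3.93), the sterol hydroxylase gene Cyp27a1 (-3.49, from 65.53 ± 24.3 to 4.619 ± 0.711 CPM) and Mamdc2 (-3.4). Cd274 stood at 221.1 ± 22.9 CPM in untreated wells, a log2 fold change of 1.57 (SE 0.15, limma adjusted p = 1.4e-05), and Cd80 rose by 0.93. In all 5830 of 13728 genes (42.5%) changed in limma with Benjamini-Hochberg adjustment, 3018 higher and 2812 lower.

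Of the cytokine and chemokine genes 19 of 23 rose, of the NF-kB genes 18 of 20, of the interferon-stimulated genes 32 of 34 and of the glycolysis genes 18 of 20, with no falls in these lists except 1 glycolysis gene under total-count or upper-quartile scaling. Adjusted over the list alone the rises were 19, 18, 33 and 18. Camera adjusted p-values were 2.4e-11, 8.34e-12, 1.65e-16 and 1.32e-13, and with an estimated correlation the adjusted p = 0.19, 0.232, 0.269 and 0.19. MHC class I genes rose in 15 of 18 cases (16 adjusted over the list alone; camera adjusted p = 9.7e-07, adjusted p = 0.284 with an estimated correlation), while MHC class II genes fell in 9 of 11 (11 adjusted over the list alone; camera adjusted p = 2.39e-05, adjusted p = 0.269 with an estimated correlation). Cell cycle genes fell in 23 of 43 cases and rose in 2 (24 and 2 adjusted over the list alone; camera adjusted p = 2.39e-05, adjusted p = 0.293 with an estimated correlation). Lipid handling genes fell in 13 of 26 and rose in 2 (14 and 2 adjusted over the list alone; camera adjusted p = 4.13e-05, adjusted p = 0.289 with an estimated correlation). Cell cycle inhibitors and p53 targets passed here, with 9 of 23 falling and 3 rising, also when adjusted over the list alone (camera adjusted p = 0.0152, adjusted p = 0.289 with an estimated correlation); whether they differ from the comparison with isotype antibody was not tested.

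Costimulatory and checkpoint genes rose in 10 of 18 cases and fell in 2, apoptosis regulators rose in 11 of 23 and fell in 4, and Fc and complement receptor genes rose in 12 of 21 and fell in 4. Adjusted over the list alone these were 10 and 2, 11 and 4, and 13 and 4. Their camera adjusted p-values were 0.0093, 0.0358 and 0.00291, and with an estimated correlation the adjusted p = 0.23, 0.293 and 0.293. The summed level of this last list was 11300 CPM in untreated 7, against 17710 and 17820 CPM in untreated 8 and 9 and 18010 to 18340 CPM with the PD-L1 antibody; without untreated 7 the counts were 12 and 4. C3, the central complement component, went from 362.4 ± 136 to 1454 ± 26.3 CPM. The PI3K list (14 up and 6 down of 31, camera adjusted p = 0.0566), alternative activation (7 and 7 of 20, 0.976), cholesterol genes (7 and 2 of 22, 0.277) and macrophage identity (4 and 6 of 17, 0.353) did not pass, with 14 and 6, 7 and 7, 7 and 2, and 4 and 6 when adjusted over the list alone. Without PD-L1 antibody 1 or untreated 8 only 4 cholesterol genes rose, and without PD-L1 antibody 3 or untreated 9 only 2 macrophage identity genes did. Scaling by total counts moved the split of calls to 1939 higher and 4089 lower and upper-quartile scaling to 2405 and 3427, and edgeR on summed deposited read counts called 4898 genes (2501 higher, 2397 lower).

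The comparison of isotype antibody with untreated wells asks what antibody protein without an intended target changed. A single gene passed, the immediate early transcription factor gene Fosb, at 20.75 ± 2.65 CPM with the isotype antibody and 1.847 ± 1.47 CPM untreated (log2 fold change 3.05, SE 0.32, limma adjusted p = 0.0173). Fosb was at 22.75 ± 8.27 CPM with the PD-L1 antibody. Cd274 was at 226.5 ± 44.6 and 221.1 ± 22.9 CPM (limma adjusted p = 0.967), and Cd80, Pdcd1lg2 and Pdcd1 had limma adjusted p-values of 0.929, 0.897 and 0.584. None of the 23 cytokine and chemokine genes passed, and the median of that list was -0.16.

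Among complement and lipid-handling genes the untreated libraries were spread widely for some, such as C1qa and Apoe. For others they lay close, such as Lipa at 1088.71, 992.316 and 1020.305 CPM in untreated 7, 8 and 9. C1qa, a complement C1q chain gene, stood at 291.5 ± 181 CPM with the isotype antibody and 849.2 ± 530 CPM untreated (limma adjusted p = 0.362), and Apoe, the apolipoprotein E gene, at 5482 ± 2230 and 12080 ± 6520 CPM (limma adjusted p = 0.38). Fos (267 ± 19.4 and 183.8 ± 31.8 CPM) and Egr1 (14.88 ± 1.29 and 9.534 ± 1.89 CPM), immediate early genes like Fosb, each had a limma adjusted p = 0.346. Of the heat shock and immediate early list 1 of 18 members rose (3 adjusted over the list alone), with a camera adjusted p = 0.031 and an adjusted p = 0.657 with an estimated correlation.

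In all 10 of 28 lists passed camera with its preset correlation, 3 upward and 7 downward, and with an estimated correlation none did (lowest adjusted p = 0.657), nor with fry. Besides the immediate early list they were the PI3K list (median 0.11) and neutrophil markers (0.31) upward, and downward the cytokine list, MHC class I (-0.15), cell cycle inhibitors (-0.12) and the markers of B cells (-0.37), T and NK cells (-0.29), stromal cells (-0.44) and erythroid cells (-0.41), where no member passed by itself; adjusted over the list alone 2 neutrophil markers rose, and 1 T and NK cell marker and 2 stromal markers fell. The summed B cell markers stood at 85.9 ± 5.2 CPM with the isotype antibody and 110 ± 24 CPM untreated. Among them Blnk was at 66.447 to 77.248 and 66.776 to 99.545 CPM. The summed T and NK cell markers were low, at 16.5 ± 6.3 and 26.8 ± 5.4 CPM, with Cd4 at 2.769 to 8.205 and 7.34 to 17.372 CPM. Without isotype 5 the lists that passed numbered 5, and without untreated 9 they numbered 6. At an unadjusted p under 0.05 limma gave 1745 genes (12.7%), and edgeR on summed deposited read counts called 2 genes, Mir7213 and Snora69, small RNA genes chosen here only because the count is low.

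The number of calls rested on untreated 7. Without it limma called 2297 genes (1339 higher, 958 lower), and the Fosb call was lost without PD-L1 antibody 1, any isotype antibody library, untreated 8 or untreated 9, where its log2 fold change was 2.75 to 3.15.

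Changes against the shared untreated libraries were compared across the 13728 genes, which are not independent replicates. The log2 fold changes of the PD-L1 antibody and of the isotype antibody had a Pearson r of 0.284, against 0.499 simulated for unchanged groups that share these controls. Their covariance was 0.0391, against a simulated 0.0109 (0.0102 to 0.0115 over 100 draws), a difference of 0.0282. The draws gave all groups the same spread and treated genes as independent. The untreated libraries were spread more, with root mean square log2 differences of 0.38 and 0.384 between untreated 7 and untreated 8 and 9. Between isotype antibody libraries the largest was 0.27. The simulated covariance may therefore be too low and its range too narrow. Fosb was the 1 gene called in both, with 0.22 expected from independent lists, and the 3 controls could not be divided into parts of 2, so part of the excess may come from the shared controls. Without untreated 7 the r was 0.435 and without untreated 8 it was 0.174.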

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

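The tests of antibody contact, neutrophils, antibody preparation, scaling, label and depth, and the look at reads outside exons, were chosen only after the results were seen; those of granulocyte precursors and of GC content and length were not, except for leaving out isotype 4, which was also chosen afterwards.

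Reads outside annotated exons were taken as the reads over a gene's span minus its exonic read equivalents. Spliced gaps and exons of other isoforms also enter this remainder, so it can rise with the exonic signal itself. It is therefore not independent of the comparisons. These reads were higher with the PD-L1 antibody for many genes. Of 1932 genes that rose against the isotype antibody and overlap no other gene, 1453 (75.2%) had such reads above all 6 control libraries in all 3 PD-L1 antibody libraries. Among genes with a limma adjusted p of at least 0.5 this held for 73 of 2688 (2.7%), against 1.19% by chance.

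With the PD-L1 antibody 21 of 23 inflammatory cytokine and chemokine genes rose (adjusted p = 0.146 with an estimated correlation). For this list, contact with any antibody protein is argued against by the isotype antibody. The list median there was -0.16 against untreated wells (quartiles -0.28 to 0), and -0.1 without untreated 7. Other inflammatory genes are not covered by this. Without untreated 7, 5 of 20 NF-kB feedback and inflammatory response genes rose with the isotype antibody and 0 fell (median 0.21). Neutrophils in the PD-L1 antibody wells are argued against by their markers. The marker median against the isotype antibody was -0.57 (quartiles -1.03 to -0.02), and -0.26 without isotype 4 (quartiles -0.74 to 0.14). The abundant S100a8 stood at 89.5 against 112.3 CPM and S100a9 at 172.4 against 267.7 CPM (limma adjusted p = 0.405 and 0.0914). Without isotype 4 they stood at 89 against 87.6 CPM and 171 against 203 CPM. An immune stimulant carried by the PD-L1 antibody preparation and binding of PD-L1 itself cannot be told apart, nor can any other difference between the antibodies. All 3 PD-L1 antibody libraries lay above the other 6, but each arm had 1 antibody, and binding was not tested.

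With the PD-L1 antibody 26 of 43 cell cycle genes fell and 2 rose (adjusted p = 0.261 with an estimated correlation). The median of the list was at most -0.50 over 4 scalings (quartiles -0.89 to -0.27 under the scaling that put it highest). The alternatives to TMM moved genes by a median of only -0.17 to 0.01, too little to remove the fall. The fall thus did not hinge on the choice among the 4. All are relative to the other genes of a library, so whether scaling contributes stays open. Whether fewer granulocyte precursors contribute stays open: the median of 5 precursor genes was -0.60, under that of the cell cycle list (-0.51), but without isotype 4 it was -0.31, above that list's -0.57. An effect of the antibody on macrophage division was not tested and stays open.

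Untreated 7 stood apart from untreated 8 and 9. Lower depth is argued against, since in 2053 genes of at least 100 CPM its difference from them was 3.91 times the difference between them. Whether untreated 7 was an isotype antibody library under a wrong label stays open. Its mean distance to those libraries was 0.258, where the largest distance between 2 of them was 0.27. This distance rests on the same values that placed it among them on component 2, so it is not separate evidence. Fosb was at 3.51 CPM in untreated 7 against a mean of 20.6 CPM with the isotype antibody and 1.01 CPM in untreated 8 and 9. GC content and transcript length explained 17.5% of the variance, which leaves their part open. No biological explanation was tested.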

How the results depend on the processing

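Of the alternatives, edgeR on deposited read counts (with 1 transcript per gene, and summed over transcripts), edgeR on rounded exonic reads, limma-voom on exonic reads and the pseudocounts of 0.25 and 4 were chosen after seeing the data. No paired analysis was possible because the replicate numbers run on from group to group and pair nothing. For isotype antibody against untreated wells, where limma called 1 gene, total counts only gave 2 (Fosb and C1qtnf1), no filter 2 (C1qtnf1 and Pi15), DESeq2 on deposited read counts 131 (66 higher, 65 lower), and edgeR on deposited read counts, summed or not, 2 (Mir7213 and Snora69). It was 0 with limma-voom on deposited read counts, the 6 libraries compared alone, edgeR on rounded exonic reads, limma-voom on exonic reads and an adjusted p under 0.01. Leaving out single libraries gave 0 to 2297 genes, the highest without untreated 7. At an adjusted p under 0.01 the PD-L1 antibody changed 3223 genes against the isotype antibody and 3824 against untreated wells; leaving out single libraries gave 3772 to 6032 and 4520 to 6768. With an estimated correlation 0 lists passed in each of the 3 comparisons, and with fry 18, 20 and 0. Leaving out single libraries gave 15 to 19, 16 to 20 and 5 (without isotype 5) to 12 (without isotype 4) lists. The r between the effects of the 2 antibodies ran from 0.174 without untreated 8 to 0.435 without untreated 7. Over 2366 alternatives for 99 gene results 2345 stayed on the same side of the threshold, 17 lost the call and 4 gained it. Changes of direction were counted only where the gene was called in the main or the alternative result, and there 0 reversed. Results called in neither were not checked for direction. Those that gained the call were Apoe, C1qa, Egr1 and Fos without untreated 7, and those that lost it were Fosb, Pdcd1lg2 and Nptx1. Fosb was also lost without a filter, with the 6 libraries compared alone, and with the limma-voom and edgeR alternatives (adjusted p = 0.0538 to 0.422 where lost). Over 2856 alternatives for 168 counts of list members 2728 stayed within 1.5 times, 67 were lower and 61 higher. Where no construction shows it, the cause was not tested. Depth limits genes of few reads, whose log2 fold changes are understated.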

Other observations

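The gene values without untreated 7 and the other divisions of the libraries were tests chosen only after the results were seen. The lists of stress responses were compared between PD-L1 antibody and isotype antibody. Hmox1, the haem-degrading oxygenase gene, went from 260 ± 2.07 to 1153 ± 170 CPM, and Fth1, the ferritin heavy chain gene, from 9097 ± 547 to 28360 ± 1850 CPM, while the iron exporter gene Slc40a1 fell from 91.14 ± 15.2 to 12.48 ± 3.14 CPM. In this oxidative stress list 8 of 14 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0156, adjusted p = 0.185 with an estimated correlation). Of the hypoxia list 9 of 15 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.000458, adjusted p = 0.185 with an estimated correlation), with the prolyl hydroxylase gene Egln3 up by 2.47 and Bnip3 by 1.95; 1 fell without any 1 of the PD-L1 antibody libraries, isotype 4 or isotype 5.

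Amino acid and endoplasmic reticulum stress genes rose in 11 of 20 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.00291, adjusted p = 0.22 with an estimated correlation). The cystine transporter gene Slc7a11 went from 27.89 ± 2.98 to 118.1 ± 17.9 CPM and the stress-induced Nupr1 from 11.79 ± 1.56 to 48.6 ± 2.73 CPM. Of 18 heat shock and immediate early genes 8 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0231, adjusted p = 0.399 with an estimated correlation), with Ier3 up by 1.88 and Hsph1 by 0.98; 1 fell without any 1 of the PD-L1 antibody libraries, isotype 5 or isotype 6. Against untreated wells these 4 lists also passed in camera, with adjusted p-values of 0.00651, 0.00198, 0.00289 and 0.00229, and with an estimated correlation the adjusted p = 0.19, 0.232, 0.269 and 0.284.

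Markers of other cell types were measured in the same way against the isotype antibody. Of 15 neutrophil and granulocyte precursor markers 5 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.0517), with Ltf from 192 ± 60.7 to 44.56 ± 8.76 CPM. Of 13 dendritic cell markers 7 fell and 2 rose (8 and 2 adjusted over the list alone, median -0.74, camera adjusted p = 0.0947), while their summed level did not fall. Of 10 erythroid and megakaryocyte markers 5 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.0506); the rise was Pf4, a platelet chemokine gene, from 61.39 ± 12.1 to 313.2 ± 62 CPM. Of 9 osteoclast markers 4 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.61), with Acp5 up by 1.62 and Dcstamp down from 12.47 to 1.8 CPM. The remaining camera adjusted p-values were 0.531 for B and plasma cells (1 of 7 fell, 1 adjusted over the list alone), 0.52 for T and NK cells (1 of 9 fell, 0 adjusted over the list alone; none without PD-L1 antibody 1, PD-L1 antibody 3 or isotype 4), 0.166 for stromal and endothelial cells (5 of 13 rose and 1 fell, also adjusted over the list alone; 3 rose without PD-L1 antibody 1, PD-L1 antibody 3 or isotype 6, and none fell without PD-L1 antibody 1 or 2 or isotype 5 or 6) and 0.998 for mast cells and basophils (1 of 8 rose, 1 adjusted over the list alone; 1 fell without isotype 6 or untreated 7). Against untreated wells B and plasma cell markers (3 of 7 fell, 3 adjusted over the list alone, camera adjusted p = 0.0419, adjusted p = 0.405 with an estimated correlation; 1 without PD-L1 antibody 1 or 3) and erythroid markers (8 of 10 fell and 1 rose, 9 and 1 adjusted over the list alone, camera adjusted p = 0.00289, adjusted p = 0.284 with an estimated correlation) passed, and the other marker lists did not. Some genes stand in more than 1 list, among them Atp6v0d2, Mmp9 and Ccl17. In the erythroid list Hba-a1 and Hba-a2 had nearly the same value in every library, so 1 signal may be counted 2 times. Hbb-bs, Hbb-bt, Epor and Gp9 of that list stayed under 5 CPM in every library.

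Without untreated 7 the comparison of isotype antibody with untreated wells called 2297 genes. The genes that follow were chosen after their values were seen. C1qa stood at 290 CPM with the isotype antibody and 1140 CPM in untreated 8 and 9 (245 CPM in untreated 7), the mannose receptor gene Mrc1 at 77.5 and 250 CPM (48.9 CPM), and Apoe at 5450 and 15700 CPM (4590 CPM). Vcan, a matrix proteoglycan gene, was higher, at 31.7 and 6.22 CPM (28.8 CPM).

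With 3 libraries against 3 there are 10 divisions, so a share under 0.05 cannot be reached. The real division gave 5002 genes for PD-L1 antibody against isotype antibody and 5830 against untreated wells, each the 1 division with as many, and the highest of the others gave 0. Every other division mixes the groups, so a large difference between them enters the spread within each side. The 0 is therefore no separate evidence against chance. For isotype antibody against untreated wells 2 divisions gave as many as the real one, with 1 gene; the other, isotype 4 with untreated 8 and 9 against isotype 5 and 6 with untreated 7, gave 752 and points to a structure of the samples.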
